A study of Mus musculus with 30 samples.

How the data were processed

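Naive (TN) and in vitro differentiated memory (TMem) CD8+ T cells of Pmel-1 mice, which carry a transgenic T cell receptor, were compared on 30 arrays. Per the labels, the cells came from spleens of C57BL/6 mice given as female, and TN and TMem cells differed in the congenic marker Ly5. They were taken before stimulation or 18 h or 96 h after stimulation with antibodies to CD3 and CD28 and IL-2. In the mix groups both cell types were cultured together, and in the alone groups each was cultured by itself. Per the labels, the cells of every group were sorted by flow cytometry. Per the labels, RNA was extracted with QIAGEN kits, amplified with a whole transcript kit, labelled with biotin and hybridized to Affymetrix mouse gene arrays.

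The deposited values are log2 probe set values. Per the submitters' processing notes, RMA and Partek were used, and the versions, the order and the role of each are not given in the sources used here. RMA as commonly run corrects background, normalizes between arrays and summarizes probes on the log2 scale. All values lay between 2.05 and 14.2, and the medians of the arrays between 6.76 and 6.94, as checked on the values. The values were used as deposited. Raw image or probe files were not used here, so scan dates and detection calls are unknown, and the background of single genes could not be set. For arrays, their number of 3 per group limits the precision.

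The table held 35556 rows. Of these, 21789 named 1 gene symbol and were used, 1621 named several and were left out, and 12146 were not in the table of probes and genes. Where a gene had more than 1 row (999 genes), the row with the highest mean over all arrays stood for it, which left 19938 genes. No filter on low values was applied. By gene number, 21698 rows matched the table of gene names (mouse assembly GRCm38.p6), which was used for names and for chromosomes X and Y, and 91 did not. Of 582 members of the gene lists, 525 matched a gene and 57 did not. The latter are not reported here.

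Arrays were grouped by cell type, culture and time into 10 groups of 3. One linear model with a mean per group was fitted with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, with 20 residual degrees of freedom. All 13 comparisons of 2 groups and 3 differences between effects were contrasts of this fit, 2-sided, with Benjamini-Hochberg adjustment over all genes within a contrast. Genes were called at an adjusted p under 0.05. SE are those of the moderated fit. The 28 gene lists were written before the data were examined and tested with camera (preset correlation of 0.01), adjusted over the 28 lists within a contrast. A list of mast cell and basophil markers was added after the data were seen and used in the closing observations only. Camera with an estimated correlation and the rotation test fry served as alternatives. Some genes belong to more than 1 list, and several genes of the lists of other cell types, such as Eomes, Gzma and Cd244a, are also transcribed by CD8+ T cells.

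The memory score of an array was the mean of the genes at least 1 higher (log2) in TMem than in TN at 0 h minus the mean of those at least 1 lower. The stimulation score was built in the same way from the response to stimulation of the other cell type at the same time. Both were compared with exact 2-sided permutation tests of 3 against 3 arrays, which cannot go below p = 0.1. Effects of mixing were also compared across genes by Pearson and Spearman correlation and by shared calls, without p-values, since genes are not independent.

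Genes named in the text followed a rule fixed in advance. It took the 8 largest called rises and falls with nonoverlapping groups in the 4 comparisons of mix with alone and in TMem against TN at 0 h, the 5 largest in the other comparisons, the 4 largest in differences between effects, up to 4 members of each list with the smallest adjusted p, and 20 genes followed throughout. Symbols of the kinds Gm, Rik, LOC, Mir and Snor, segments of T cell receptors and immunoglobulins, and olfactory or vomeronasal receptors were not named among the largest. Not every gene the rule allows is printed.

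The procedure was tested on simulated data for TN mix against TN alone at 18 h. Of genes given a log2 difference of 0.5, 58.2% were recovered with the right sign (67 genes), of 1, 97.0% (67 genes), and of 2, 98.5% (66 genes). Among 176 calls 3.98% were genes made without a difference, and the median of estimated over true difference was 0.998 (200 genes). A gap of 30% put in was found as 29.8% by the memory score (1403 genes) and 29.4% by the stimulation score (1409 genes). Every gene was moved by that share, so the scores return it by construction. The hypoxia list was called, as was 1 of 26 lists that share no gene with it. Of 101 genes raised in both cell types 79 were called higher in both, and of 99 lowered 82 lower. The noise was drawn independently for each gene, with 1 SD over all groups. Measured genes are not independent and the 0 h arrays spread more, so these rates may not hold for the data.

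Whether replicate numbers pair the arrays was checked by correlating, across genes, the deviations of arrays with the same number from their group means. In TN mix against TN alone at 96 h all such correlations exceeded 0.1 (0.137 to 0.489), and in no other comparison did all of them. No arrays were duplicates (the closest pair had r = 0.996 and 0.391% identical values). The lowest correlations within a group were 0.978 in TN 0 h, 0.984 in TMem 0 h, 0.988 in TN mix 18 h and 0.990 in TN mix 96 h. Principal components took 39.9%, 26.9%, 8.96% and 5.51% of the variance.

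Alternatives fixed in advance were a filter on dim genes (a group mean above 6.87, the median of all values, which kept 11743 genes and left out 8195), quantile normalization, median centring, array weights, eBayes with trend and robust, a difference of at least 1, only the groups compared, every row of the table, the mean of all rows of a gene, a replicate block, other genes for the scores, and leaving out each array in turn. Leaving out the 0 h arrays, the pairs of TN arrays at 96 h as a block, and leaving out genes of X and Y were chosen after seeing the data. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.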

Results

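Naive (TN) and in vitro differentiated memory (TMem) CD8+ T cells were measured on 30 arrays in 10 groups of 3. Both cell types carried the same transgenic receptor. They were sampled before stimulation (0 h) and after 18 h and 96 h of stimulation, either by themselves (alone) or in culture with the other cell type (mix), and sorted before RNA was taken. The submitters' notes describe biological repeats in triplicate, so p-values measure spread between samples. All comparisons used 19938 genes, and log2 differences are given as the first group minus the second, with n = 3 arrays per group. A group mean below the mean lower quartile of the group's arrays is called near background here, since it is not shown to exceed background, and a difference from such a level is a lower bound of its size. With 3 arrays against 3 an exact permutation test cannot go below p = 0.1, so calls rest on moderated tests that pool the spread over genes and groups. The groups, comparisons, gene lists and the rule for naming genes were fixed before the data were examined.

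At 18 h, single cytokine, effector and naive T cell genes differed between TN cells from mixed cultures and TN cells stimulated alone. Il3, a growth factor for hematopoietic cells, rose by 2.01 on the log2 scale (SE 0.41), and Il2, the T cell growth factor, by 1.37 (SE 0.17). The mean of Il3 in TN alone was 5.77, just above the mean lower quartile of 5.74 that bounds near background there. Granzyme B (Gzmb), which kills target cells, rose by 1.00 (SE 0.08), and Eomes, a transcription factor of effector and memory cells, by 1.27 (SE 0.09). The receptor for the survival cytokine IL-7 (Il7r) fell by 1.61 (SE 0.16). Lef1 and Klf2, transcription factors that keep T cells naive and recirculating, fell by 0.93 and 0.90.

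Other large rises were Cd24a (1.83), Cd83 (1.74), Cd200 (1.46), Serpinb9 (1.46), Scd2 (1.39) and Serpinb6b (1.36). Cd24a, Cd83 and Cd200 encode surface molecules, Serpinb9 protects cells from their own granzyme B, and Scd2 desaturates fatty acids. Large falls besides Il7r were Akr1c18 (-1.74), Kif21b (-1.53), Cd7 (-1.53), Slc12a7 (-1.51), Pde2a (-1.49), Tmem71 (-1.42) and Cdc25b (-1.40). Of the genes followed in every comparison, Cd44, a marker of antigen-experienced cells, rose by 0.77, the death receptor Fas by 0.85 and Tbx21, the gene of T-bet, by 0.46. Perforin (Prf1, log2 difference -0.04), Fasl (0.09), Ccr7 (0.21), Cd27 (-0.21), Prdm1 (-0.16), Il2ra (0.19), Ptprc (-0.15), Cd8a (-0.00) and Cd8b1 (-0.02) were not called. Interferon gamma (Ifng) was higher by 1.14 with an adjusted p = 0.0927. Ifng (adjusted p 1.17e-09 to 0.218) was called with array weights, with only the groups compared, and with the 0 h arrays left out of the fit, a setting chosen after the data were seen. Ccr7 (adjusted p 0.028 to 0.564) and Il2ra (adjusted p 0.0239 to 0.349) were called with array weights and with the 0 h arrays left out. Ranges are over all alternatives of a gene. The SD of Ifng among the TMem arrays at 0 h was 1.89, against 0.18 in TN alone at 18 h.

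Among the preset lists at 18 h, cytokines and chemokines were higher as a set (adjusted p = 4.80e-04, adjusted p = 0.205 with an estimated correlation). Of its genes 9 of 24 rose and 0 fell, 10 and 0 adjusted over the list alone, with Ccl9 (0.94) and Lta (0.53) beside Il2 and Il3. Of the naive and central memory genes, 1 of 20 rose and 10 fell, 1 and 10 adjusted over the list alone, and the set was lower (adjusted p = 3.61e-07, adjusted p = 0.205 with an estimated correlation). Il6ra (-1.29) and S1pr1 (-1.20) were among those that fell, beside Il7r, Lef1 and Klf2. Of the genes of ribosome assembly, 12 of 24 rose and 0 fell, 15 and 0 adjusted over the list alone, among them Wdr12 (0.72), Nop16 (0.49), Dkc1 (0.47) and Nop56 (0.30). The set was higher (adjusted p = 4.79e-09, adjusted p = 0.205 with an estimated correlation). In the electron transport chain, 10 of 31 rose and 0 fell, 13 and 0 adjusted over the list alone, including Sdhd (0.78), Ndufb3 (0.75), Ndufv2 (0.52) and Uqcrc2 (0.33) (adjusted p = 1.39e-07, adjusted p = 0.398 with an estimated correlation). Granzymes and cytotoxic molecules were higher as a set (adjusted p = 0.00675, adjusted p = 0.398 with an estimated correlation), and 5 of 18 rose and 2 fell, 5 and 2 adjusted over the list alone, with Gzmc (1.35) rising and Tnfsf10 (-0.57) falling. T cell activation genes (4 of 19 rose and 1 fell, 6 and 1 adjusted over the list alone) were higher (adjusted p = 0.0024, adjusted p = 0.385 with an estimated correlation), with Tfrc (0.71) and Cd69 (0.60) beside Cd83.

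Cell cycle genes of S phase (6 of 23 rose and 0 fell, 7 and 0 adjusted over the list alone, adjusted p = 1.79e-04, adjusted p = 0.205 with an estimated correlation) and of G2 and M phase (4 of 23 rose and 1 fell, 5 and 1 adjusted over the list alone, adjusted p = 0.00939, adjusted p = 0.429 with an estimated correlation) were higher at 18 h, with Rfc3 (0.73), Prim1 (0.70) and Top2a (0.40). Higher sets were also cholesterol synthesis (8 of 19 rose and 2 fell, 10 and 2 adjusted over the list alone, adjusted p = 0.00262, adjusted p = 0.385 with an estimated correlation) and amino acid response and ATF4 targets (5 of 21 rose and 2 fell, 5 and 2 adjusted over the list alone, adjusted p = 0.0364, adjusted p = 0.467 with an estimated correlation). So were handling stress genes (3 of 13 rose and 1 fell, 6 and 1 adjusted over the list alone, adjusted p = 0.00675, adjusted p = 0.205 with an estimated correlation). Effector transcription factors and receptors were not called as a set (adjusted p = 0.214), although 5 of 23 rose and 3 fell, 6 and 3 adjusted over the list alone, with Bhlhe40 (1.05) up and Klrd1 (-1.25) down. The lists for the Fas and death receptor pathway (adjusted p = 0.0906), inhibitory receptors (adjusted p = 0.543), glycolysis (adjusted p = 0.219), hypoxia (adjusted p = 0.466), fatty acid oxidation (adjusted p = 0.84), IL-2 and STAT5 response (adjusted p = 0.184) and p53 targets (adjusted p = 0.0582) were not called. Neither were the type I (adjusted p = 0.0948) and interferon gamma (adjusted p = 0.543) responses, the unfolded protein response (adjusted p = 0.729) and ribosomal proteins (adjusted p = 0.336). Median and mean differed in sign for inhibitory receptors (-0.07 and 0.08), fatty acid oxidation (0.08 and -0.01), IL-2 and STAT5 response (-0.00 and 0.09), unfolded protein response (-0.01 and 0.02) and NK cells (-0.07 and 0.06). Within fatty acid oxidation, Cpt1a, which admits fatty acids to mitochondria, fell by 0.98. The lists of B cells (adjusted p = 0.855), macrophages and related cells (adjusted p = 0.82), NK cells (adjusted p = 0.719), CD4 T cells (adjusted p = 0.291) and erythroid cells and platelets (adjusted p = 0.82) were not called at 18 h, although Cd74, the invariant chain of MHC class II, rose by 0.72.

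At an adjusted p under 0.05, 1257 genes were higher and 1624 lower in TN mix than in TN alone at 18 h, of which 31 and 85 differed by at least 1 on the log2 scale. The 3 values of each group did not overlap for 34.1% of genes, where chance gives 10%. The count of 2881 became 1897 without TN alone 18 h replicate 2 and 4853 with array weights. Some calls were lost when 1 array was left out, given here with the range of adjusted p over the alternatives of the gene. The call of Tbx21 was lost without TN alone 18 h replicates 1, 2 or 3 or TN mix 18 h replicates 1, 2 or 3 (adjusted p 3.77e-06 to 0.0883) and with quantile normalization (adjusted p = 0.0783). That of Cd44 was lost without TN alone 18 h replicates 1 or 2 or TN mix 18 h replicates 2 or 3 (adjusted p 6.83e-05 to 0.0835). That of Ndufb3 was lost without TN alone 18 h replicate 2 or TN mix 18 h replicate 1 (adjusted p 3.01e-06 to 0.0806) and that of Top2a without TN alone 18 h replicate 2 (adjusted p 6.27e-05 to 0.0731). With each array centred on its median, 1530 genes were higher and 1287 lower, or 54.3% higher against 43.6%. 11 of 28 lists were called with the preset correlation and 0 with the estimated one.

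**Figure D1:**
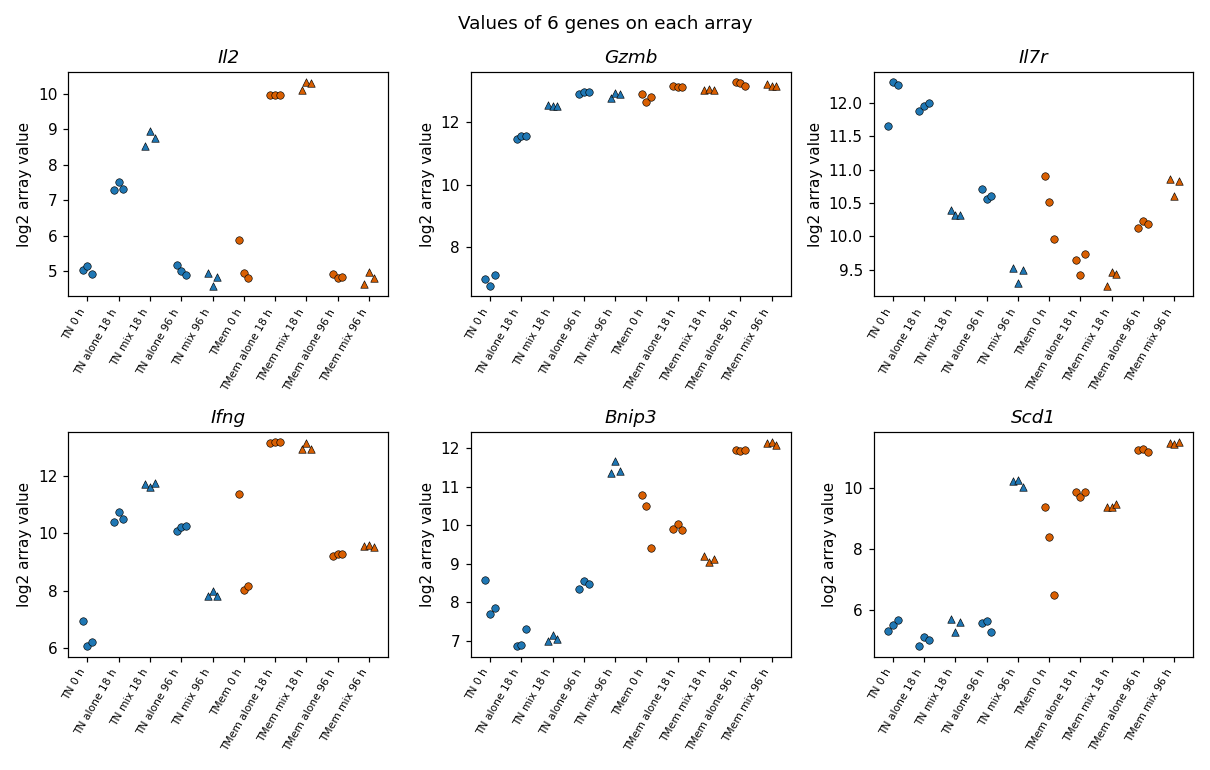
Log2 array values of 6 genes on all 30 arrays. Blue, TN; orange, TMem; circles, 0 h and alone; triangles, mix; each point is 1 array, 3 per group. Il2 was higher in TN mix than in TN alone at 18 h by 1.37, and Scd1 and Bnip3 at 96 h by at least 4.69 and by 3.02.

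At 96 h, TN cells from mixed cultures carried more transcripts of cholesterol synthesis, glycolysis and the response to low oxygen. Scd1, which desaturates fatty acids, rose by at least 4.69 on the log2 scale (SE 0.35) from a mean of 5.49 in TN alone, a level near background. Bnip3, a mitophagy gene induced by hypoxia, rose by 3.02 (SE 0.22). The chemokine receptor Ccr2 rose by 2.33 (SE 0.33) and the death ligand Fasl by 1.38 (SE 0.21). Ifng fell by 2.32 (SE 0.45), and the integrin Itgae, which holds T cells in epithelia, by 2.06 (SE 0.27). Gzmb was not called (log2 difference -0.08, SE 0.08, adjusted p = 0.637).

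Further large rises were Ak4 (3.49), Mt2 (3.44), Asns (2.81), Zdhhc2 (2.78) and Aldoc (2.70). Ak4 is a mitochondrial adenylate kinase, Mt2 binds zinc, Asns makes asparagine and Aldoc belongs to glycolysis. Other large falls were H2-Aa (-2.83), Lyz2 (-2.79), Gpr83 (-2.49), Gria3 (-2.26), Xcl1 (-1.97) and Lgals3 (-1.90), with Lyz2 and Gria3 near background in TN mix. Il7r and Klf2 fell by 1.19 and 0.68, and Eomes (0.32) and Prdm1 (0.48) rose. Prf1 (0.22), Cd44 (0.46), Tbx21 (0.23), Lef1 (-0.21), Ccr7 (-0.29), Cd27 (0.19), Fas (0.03), Il2ra (0.07), Ptprc (0.01), Cd8a (-0.09) and Cd8b1 (-0.13) were not called.

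All 19 measured genes of cholesterol synthesis rose at 96 h (19 adjusted over the list alone), among them Insig1 (1.46), Hmgcs1 (1.36), Sqle (1.11) and Stard4 (0.97) (adjusted p = 3.90e-36, adjusted p = 5.84e-05 with an estimated correlation). In the hypoxia response 18 of 21 rose and 0 fell, 18 and 0 adjusted over the list alone, with Egln3 (2.30), Ndrg1 (1.27) and P4ha1 (1.24) beside Bnip3 (adjusted p = 1.69e-27, adjusted p = 2.38e-04 with an estimated correlation). In glycolysis 15 of 17 rose and 0 fell, 16 and 0 adjusted over the list alone, including the transporters Slc16a3 (2.24), Slc2a3 (1.83) and Slc2a1 (1.43) (adjusted p = 8.31e-22, adjusted p = 0.00414 with an estimated correlation). Amino acid response and ATF4 targets followed (13 of 21 rose and 0 fell, 14 and 0 adjusted over the list alone, adjusted p = 1.45e-09, adjusted p = 0.0126 with an estimated correlation), with Chac1 (1.16), Slc1a4 (1.08) and Trib3 (0.69) beside Asns. Inhibitory receptors were lower (1 of 13 rose and 6 fell, 1 and 8 adjusted over the list alone, adjusted p = 3.35e-05, adjusted p = 0.00497 with an estimated correlation): Pdcd1 (-0.94), Cd244a (-0.90) and Cd200 (-0.88) fell, and Entpd1 (1.24) rose. Handling stress genes, which respond to cell preparation, were higher (7 of 13 rose and 0 fell, 8 and 1 adjusted over the list alone, adjusted p = 1.19e-04, adjusted p = 0.0124 with an estimated correlation), with Atf3 (1.61), Fosb (1.34) and Fos (0.96).

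Granzymes and cytotoxic molecules were higher at 96 h (9 of 18 rose and 2 fell, 9 and 2 adjusted over the list alone, adjusted p = 0.0191, adjusted p = 0.324 with an estimated correlation), with Serpinb6b (1.59) and Gzmk (1.25) up and Tnfsf10 (-0.96) down. Effector transcription factors and receptors were higher (8 of 23 rose and 1 fell, 8 and 1 adjusted over the list alone, adjusted p = 0.0036, adjusted p = 0.351 with an estimated correlation), with Cxcr3 (1.12) and Bhlhe40 (0.90) beside Ccr2. Naive and central memory genes were lower (3 of 20 rose and 8 fell, 3 and 12 adjusted over the list alone, adjusted p = 1.48e-04, adjusted p = 0.23 with an estimated correlation), with Il6ra (-1.21) and S1pr1 (-1.15) falling and Satb1 (0.63) rising. T cell activation genes were lower (4 of 19 rose and 7 fell, 4 and 8 adjusted over the list alone, adjusted p = 0.0164, adjusted p = 0.324 with an estimated correlation), with Nr4a3 (-1.42), Nr4a1 (-1.03) and Egr3 (-0.62) down and Egr1 (0.81) up. Lower sets with smaller medians were p53 targets (-0.14, adjusted p = 8.50e-05, adjusted p = 0.0709 with an estimated correlation) and ribosome assembly (-0.14, adjusted p = 2.48e-04, adjusted p = 0.246 with an estimated correlation). Ribosomal proteins (-0.09, adjusted p = 1.55e-04, adjusted p = 0.267 with an estimated correlation), oxidative phosphorylation (-0.10, adjusted p = 0.023, adjusted p = 0.592 with an estimated correlation) and IL-2 and STAT5 response (-0.09, adjusted p = 0.0449, adjusted p = 0.306 with an estimated correlation) were lower too. Cytokines and chemokines (adjusted p = 0.0765), fatty acid oxidation (adjusted p = 0.963), the unfolded protein response (adjusted p = 0.963), the Fas pathway (adjusted p = 0.963), both interferon lists (adjusted p = 0.16 for type I and adjusted p = 0.0729 for interferon gamma) and both cell cycle lists (adjusted p = 0.0552 for S phase and adjusted p = 0.0729 for G2 and M phase) were not called.

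Some transcripts listed for other cell types were lower in TN mix than in TN alone at 96 h. The B cell list (0 of 15 rose and 5 fell, 0 and 5 adjusted over the list alone) was lower as a set (adjusted p = 1.55e-04, adjusted p = 0.0475 with an estimated correlation), although its median was 0.06 and its mean -0.42. Those that fell included the MHC class II genes Cd74 (-1.83), H2-Ab1 (-1.25) and H2-Eb1 (-1.09) beside H2-Aa, and Cd79b (-0.70), chosen after its values were seen. The list of macrophages, monocytes, dendritic cells and neutrophils (0 of 22 rose and 3 fell, 0 and 3 adjusted over the list alone) was lower (adjusted p = 0.00218, adjusted p = 0.281 with an estimated correlation), with Fcer1g (-1.36) falling beside Lyz2 and Lgals3. The NK cell list (1 of 11 rose and 4 fell, 1 and 5 adjusted over the list alone) was lower (adjusted p = 1.40e-06, adjusted p = 0.0364 with an estimated correlation), with Klrb1b (-1.67) and Ncr1 (-0.93) falling to levels near background and Eomes rising. The CD4 T cell list (0 of 10 rose and 4 fell, 2 and 4 adjusted over the list alone) was lower (adjusted p = 0.0128, adjusted p = 0.0367 with an estimated correlation), with Foxp3 (-1.49), Izumo1r (-1.24), Tnfsf8 (-0.72) and Il17rb (-0.30) falling. The call of Tnfsf8 was lost without TN alone 96 h replicate 3 (adjusted p 4.02e-06 to 0.0676). That of Il17rb was lost without TN alone 96 h replicates 1, 2 or 3 or TN mix 96 h replicates 2 or 3 (adjusted p 1.47e-04 to 0.202), with the replicate block, with the pairs as a block, with trend and robust and with only the groups compared. The erythroid and platelet list was not called (adjusted p = 0.16). Cpa3 and Mcpt8, genes of mast cells and basophils chosen after their values were seen, fell from means of 8.58 and 7.54 in TN alone to 6.85 and 6.23 in TN mix (log2 differences -1.73 and -1.32).

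The Y-linked genes Eif2s3y (3.48), Uty (2.59) and Kdm5d (1.90) were also higher in TN mix at 96 h, from levels near background. The labels give female mice for all samples. On the arrays, TN at 0 h and TN alone at 96 h had mean Eif2s3y values of 4.19 and 4.17, against 8.14, 8.36 and 7.64 in TN alone at 18 h, TN mix at 18 h and TN mix at 96 h. The TMem groups had Eif2s3y means of 9.17 to 9.27 and Xist means of 5.26 to 5.86, where the TN groups had Xist means of 10.40 to 12.11. Y-linked transcripts thus differed between TN mix and TN alone at 96 h, and sex-linked transcripts differed between TMem and TN in every comparison of them. All TMem groups had high Y-linked and low Xist values, against the label of female mice. A difference in donors thus cannot be separated from cell type in any comparison of TMem with TN. The same holds for the genes of the memory score, which were chosen in such a comparison. Uty and Kdm5d were chosen after their values were seen.

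At 96 h, 1395 genes were higher and 722 lower in TN mix than in TN alone, 117 and 72 of them by at least 1 on the log2 scale. Groups did not overlap for 27.8% of genes, against 10% by chance. The count of 2117 was 3208 with the 0 h arrays left out of the fit and 6343 with array weights. Here the deviations of arrays with the same replicate number were correlated (0.137 to 0.489), though the labels do not say what the numbers mark. With arrays of the same number as a block the count was 2189 and Prdm1 was not called (adjusted p = 0.0564). Prdm1 was not called without TN alone 96 h replicates 1, 2 or 3 or TN mix 96 h replicates 1, 2 or 3 (adjusted p 1.65e-05 to 0.113). Eomes was not called without TN alone 96 h replicate 3 or TN mix 96 h replicate 2 (adjusted p 3.85e-04 to 0.0626). Cd44 (adjusted p 0.00756 to 0.39), Lef1 (adjusted p 0.00177 to 0.371) and Ccr7 (adjusted p 4.76e-05 to 0.39) were called with array weights and with the 0 h arrays left out, and Cd44 also with only the groups compared. Prf1 (adjusted p 0.0195 to 0.609) and Tbx21 (adjusted p 0.00749 to 0.56) were called with the 0 h arrays left out and under no other alternative tried.

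**Figure D2:**
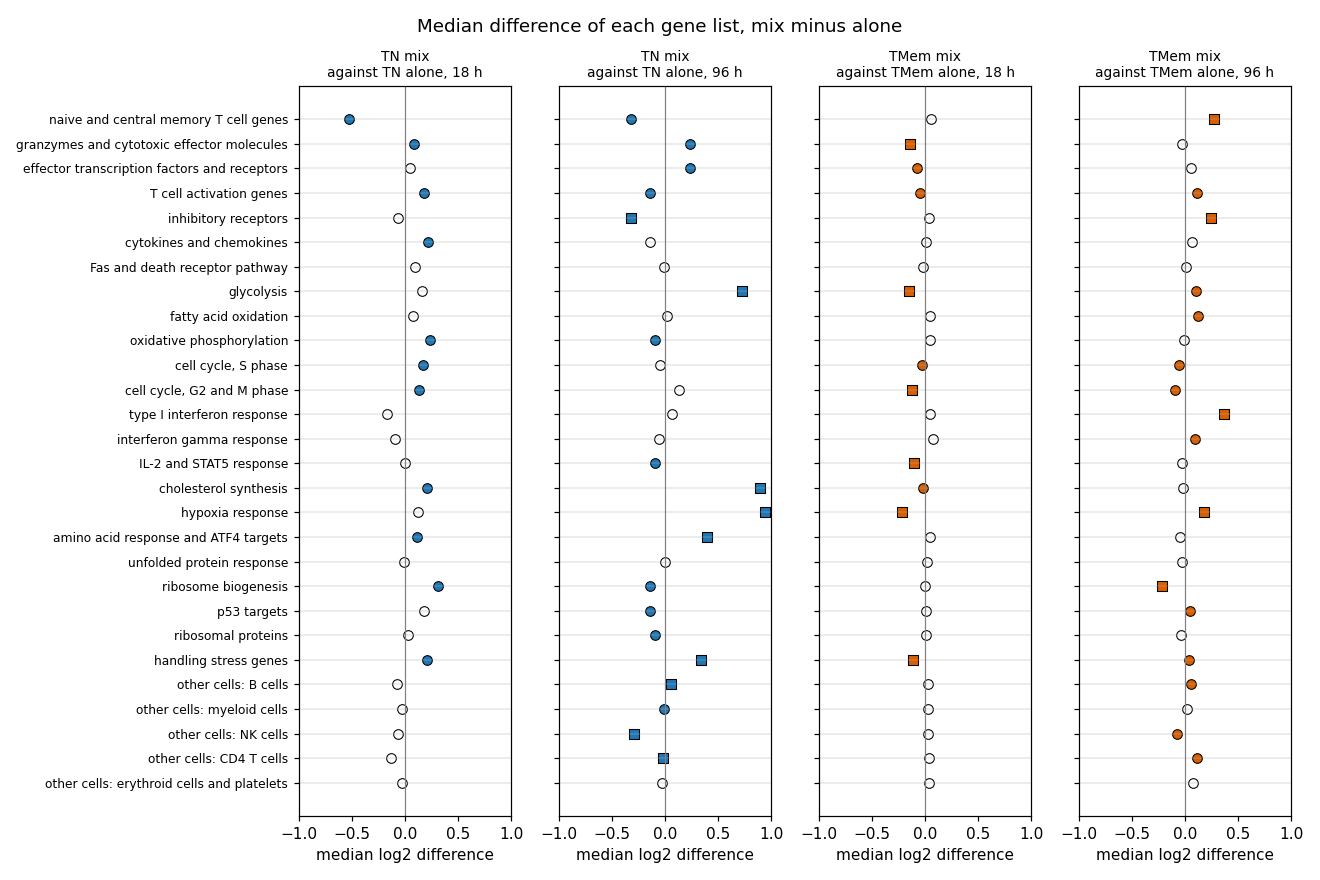
Median log2 difference, mix minus alone, over the members of each of 28 gene lists. Filled, called with the preset correlation; square, called also with an estimated correlation; open, not called; 3 arrays per group. In TN at 96 h the medians of cholesterol synthesis, hypoxia response and glycolysis were 0.89, 0.94 and 0.72.

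In TMem cells at 18 h, few transcripts differed between mixed and separate cultures. The granzymes Gzmd and Gzme fell by 1.10 and 0.87 on the log2 scale (SE 0.19 and 0.14). Il12rb2, a chain of the IL-12 receptor, fell by 0.67 (SE 0.12). Tcta, H1f2 and Cytip fell by 0.84, 0.72 and 0.51. Gzmb (log2 difference -0.11), Ifng (-0.15), Prf1 (-0.09), Il7r (-0.22), Eomes (0.07) and Cd44 (-0.17) were not called.

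As sets, the granzymes (adjusted p = 2.00e-11, adjusted p = 0.0117 with an estimated correlation), hypoxia response (adjusted p = 9.17e-17, adjusted p = 0.00778 with an estimated correlation) and glycolysis (adjusted p = 3.35e-11, adjusted p = 0.0354 with an estimated correlation) were lower in TMem mix at 18 h. The same held for cell cycle genes of G2 and M phase (adjusted p = 4.05e-10, adjusted p = 0.0193 with an estimated correlation), IL-2 and STAT5 response (adjusted p = 1.06e-06, adjusted p = 0.0166 with an estimated correlation) and handling stress genes (adjusted p = 3.08e-05, adjusted p = 0.0117 with an estimated correlation). Their medians lay between -0.21 for hypoxia and -0.11 for the IL-2 and STAT5 response. Bnip3 (adjusted p 1.73e-04 to 1) was called with array weights, with only the groups compared and with the 0 h arrays left out. In the fit of all arrays Bnip3 had a log2 difference of -0.82 (SE 0.22) and an adjusted p = 0.467. Of the hypoxia genes, 0 fell over all genes tested and 3 when adjusted over the hypoxia list alone. Effector transcription factors (adjusted p = 6.78e-05, adjusted p = 0.402 with an estimated correlation), T cell activation (adjusted p = 0.013, adjusted p = 0.47 with an estimated correlation), S phase (adjusted p = 0.0195, adjusted p = 0.47 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.0225, adjusted p = 0.531 with an estimated correlation) were lower with the preset correlation and not with an estimated one. With the rotation test fry none of the 28 lists passed.

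Over all genes, 0 were higher and 6 lower by limma, the 6 named above, with 604 at an unadjusted p under 0.05. Groups did not overlap for 12.1% of genes, against 10% by chance. The count was 41 with the 0 h arrays left out of the fit, 36 with only the groups compared, 100 with array weights, and 3 when every row of the table was tested. The call of Gzmd was lost without TMem mix 18 h replicates 1 or 2 or TMem alone 18 h replicates 2 or 3 (adjusted p 0.00103 to 0.212). That of Gzme was lost without TMem mix 18 h replicates 1 or 3 or TMem alone 18 h replicates 2 or 3 (adjusted p 9.25e-04 to 0.122). That of H1f2 was lost without TMem mix 18 h replicates 1 or 2 or TMem alone 18 h replicates 1, 2 or 3 (adjusted p 1.53e-05 to 0.236), and that of Il12rb2 without TMem mix 18 h replicates 1 or 2 or TMem alone 18 h replicates 1, 2 or 3 (adjusted p 3.58e-06 to 0.212). That of Cytip was lost without TMem mix 18 h replicates 1 or 2 or TMem alone 18 h replicate 2 (adjusted p 3.58e-06 to 0.063). With quantile normalization 1 gene was higher and 6 were lower. The count was 1 without TMem mix replicate 1 and 2 without TMem mix replicate 2, TMem alone replicate 2 or TMem alone replicate 3.

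At 96 h, TMem cells from mixed cultures carried more transcripts of inhibitory receptors, naive and central memory genes and type I interferon targets. Ctla4, an inhibitory receptor, rose by 1.44 on the log2 scale (SE 0.14). Ifit3, an interferon target, rose by 1.14 (SE 0.18), Dapl1 by 1.12 (SE 0.11) and the costimulatory receptor Cd27 by 0.78 (SE 0.10). Other large rises were Mgarp (1.21), Nrn1 (1.10), Aldoc (1.05), Kcnma1 (1.05) and Klhl24 (0.96). Large falls were those of the histone genes H3c4 (-0.90), H2bc8 (-0.82) and H1f3 (-0.71), followed by Dancr (-0.60), Ppp2r2c (-0.55), Rnf225 (-0.54), Tmem14c (-0.49) and Pprc1 (-0.49). The rows of the array for Kcnma1 disagreed in direction.

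Type I interferon response genes were higher (8 of 25 rose and 0 fell, 13 and 0 adjusted over the list alone, adjusted p = 1.30e-24, adjusted p = 0.00554 with an estimated correlation), with Rtp4 (0.88), Ifit1 (0.87) and Dhx58 (0.65). Naive and central memory genes were higher (6 of 20 rose and 0 fell, 9 and 0 adjusted over the list alone, adjusted p = 1.62e-20, adjusted p = 0.00554 with an estimated correlation), with Slamf6 (0.91) and S1pr1 (0.54) beside Dapl1 and Cd27. Inhibitory receptors were higher (4 of 13 rose and 0 fell, 4 and 1 adjusted over the list alone, adjusted p = 5.99e-08, adjusted p = 0.00155 with an estimated correlation), with Btla (0.66), Lag3 (0.48) and Pdcd1 (0.44), and so was the hypoxia response (3 of 21 rose and 0 fell, 9 and 1 adjusted over the list alone, adjusted p = 2.22e-11, adjusted p = 0.0148 with an estimated correlation), with Ndrg1 (0.91) and P4ha2 (0.67). Ribosome assembly was lower (-0.22, adjusted p = 2.22e-11, adjusted p = 0.0353 with an estimated correlation). With the preset correlation alone, T cell activation (adjusted p = 2.65e-05, adjusted p = 0.125 with an estimated correlation), glycolysis (adjusted p = 0.00116, adjusted p = 0.339 with an estimated correlation) and fatty acid oxidation (adjusted p = 4.95e-04, adjusted p = 0.339 with an estimated correlation) were higher. So were p53 targets (adjusted p = 0.00785, adjusted p = 0.303 with an estimated correlation), interferon gamma response (adjusted p = 0.0477, adjusted p = 0.492 with an estimated correlation) and handling stress genes (adjusted p = 0.0498, adjusted p = 0.256 with an estimated correlation). Genes of S phase (adjusted p = 0.0219, adjusted p = 0.342 with an estimated correlation) and of G2 and M phase (adjusted p = 0.0498, adjusted p = 0.463 with an estimated correlation) were lower with the preset correlation alone. Il7r (log2 difference 0.59, adjusted p = 0.0736), Gzmb (-0.05), Prf1 (-0.07), Ifng (0.29) and Eomes (-0.22) were not called. Among lists of other cell types, H2-Ab1 (0.92) and Cd79b (0.48) of the B cell list rose and the set was higher (adjusted p = 0.0281, adjusted p = 0.303 with an estimated correlation). The CD4 T cell list was higher (adjusted p = 0.0498, adjusted p = 0.125 with an estimated correlation) and the NK cell list lower (adjusted p = 0.0498, adjusted p = 0.439 with an estimated correlation).

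In all, 193 genes were higher and 30 lower in TMem mix than in TMem alone at 96 h, with nonoverlapping groups for 21.5% of genes against 10% by chance. The count of 223 was 507 with the 0 h arrays left out, 435 with only the groups compared and 906 with array weights. It was 105, 148 and 126 without TMem alone replicates 1, 2 and 3, and 125 and 136 without TMem mix replicates 1 and 2. Pdcd1 was not called without TMem alone 96 h replicates 1, 2 or 3 or TMem mix 96 h replicates 1, 2 or 3 (adjusted p 0.00313 to 0.33), nor with the replicate block (adjusted p = 0.0617). Dancr was not called without TMem alone 96 h replicates 1, 2 or 3 or TMem mix 96 h replicates 1, 2 or 3 (adjusted p 3.33e-05 to 0.157). The call of Btla was lost without TMem alone 96 h replicate 3 or TMem mix 96 h replicate 1 (adjusted p 4.33e-05 to 0.074) and that of Cd79b without TMem alone 96 h replicate 1 or TMem mix 96 h replicate 1 (adjusted p 3.80e-04 to 0.0857). H2bc8 was not called without TMem alone 96 h replicates 1 or 3 or TMem mix 96 h replicate 3 (adjusted p 2.56e-06 to 0.108). Ppp2r2c was not called without TMem alone 96 h replicates 2 or 3 or TMem mix 96 h replicates 2 or 3 (adjusted p 0.00107 to 0.157). Pprc1 was not called without TMem alone 96 h replicates 1, 2 or 3 or TMem mix 96 h replicates 2 or 3 (adjusted p 1.46e-04 to 0.102). Tmem14c was not called without TMem alone 96 h replicates 2 or 3 or TMem mix 96 h replicate 1 (adjusted p 2.20e-04 to 0.0902). Il7r (adjusted p 2.23e-04 to 0.328) was called with the dim filter, array weights, only the groups compared and the 0 h arrays left out, and Ifng (adjusted p 0.0489 to 1) with only the groups compared.

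The effect of mixing was compared between the cell types and between the times by contrasts of the differences themselves. At 18 h the effect in TN exceeded that in TMem for Il3 (2.25), Tnfsf4 (1.85), Cd83 (1.83) and Gzmc (1.78), Eomes (difference of the effects 1.20, SE 0.12) and Gzmb (1.10, SE 0.11), and lay below it for Akr1c18 (-1.83) and Cd7 (-1.81), Il7r (-1.39), Klf2 (-1.01) and Lef1 (-0.92). At 96 h it lay below that in TMem for Il7r (-1.77), Klf2 (-0.89), Cd27 (-0.60) and Ifng (-2.61), and above it for Scd1 (4.44) and Mt2 (3.50) and Fasl (1.60), with Scd1 near background in TN alone. The call of Cd27 was lost without TMem alone 96 h replicate 1 or TN mix 96 h replicate 3 (adjusted p 7.56e-06 to 0.0671). With median centring, 323 genes were higher and 526 lower in this contrast at 18 h, against 287 and 744. The effects differed for 1031 genes at 18 h and 705 at 96 h. Of 100 splits of the arrays, 7 gave as many genes in each of these contrasts, the real one included, and the 6 others kept the real grouping of the TN arrays and so held its effect. In TN cells the effect at 96 h differed from that at 18 h for 2475 genes. Y-linked transcripts differed between TN mix and TN alone at 96 h. A difference in donors thus cannot be separated from the effect of mixing in TN at 96 h, nor in the contrasts that use it. Gzmb (-1.07), Eomes (-0.96) and Ifng (-3.45) were lower and Fasl (1.29) and Lef1 (0.73) higher at 96 h. Inhibitory receptors moved apart as a set at 96 h, lower in TN and higher in TMem (adjusted p = 1.78e-13, adjusted p = 2.65e-05 with an estimated correlation). The effects on naive and central memory genes differed as a set at 96 h (adjusted p = 2.24e-19, adjusted p = 0.00424 with an estimated correlation). They were higher in TMem, whereas their fall as a set in TN was lost with an estimated correlation (adjusted p = 0.23) and 3 of 20 rose there.

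Across all genes, the effects of mixing in TN and TMem had a Pearson correlation of -0.00481 at 18 h and 0.181 at 96 h (Spearman 0.00626 and 0.146). Genes are not independent replicates. At 18 h the sign depended on single arrays, with r between -0.0464 without TMem alone replicate 1 and 0.058 without TMem alone replicate 2. At 96 h, 84 genes were higher in both cell types where independent lists would share 13.5, and 9 were lower in both (1.09 if independent). In opposite directions, 21 were lower in TN and higher in TMem (6.99 if independent) and 1 was higher in TN and lower in TMem (2.10 if independent). Within TN, the effects at 18 h and 96 h had a Pearson correlation of 0.0562 and a Spearman correlation of -0.0118. By call, 163 genes were higher at both times (87.9 if independent), 200 lower at both (58.8 if independent) and 192 lower and then higher (114 if independent), and 54 were higher and then lower (45.5 if independent). Within TMem, the correlation between the times was 0.0178 (Spearman -0.0133). Leaving out single arrays moved r at 96 h down to 0.0972 (without TMem mix replicate 2) and r within TN to between 0.00457 and 0.134 (without TN mix 96 h replicate 2 and replicate 1). Within TMem it moved to between -0.0413 and 0.0941 (without TMem mix 96 h replicate 3 and replicate 1). No pair of comparisons shared an array. However, both cell types of the mix groups were cultured together, so TN mix and TMem mix arrays may come from the same cultures. Their effects of mixing at the same time may then share differences between cultures. In addition, all calls came from 1 fit with 1 spread per gene. Genes with a small spread can thus be called in several comparisons. The counts for independent lists are therefore no chance level here.

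Before stimulation, TMem cells carried more transcripts of the cell cycle than TN cells and differed in single effector and naive T cell genes. Gzmb was higher by 5.85 on the log2 scale (SE 0.08), Il2ra, a chain of the high-affinity IL-2 receptor, by 4.42 (SE 0.08) and Ccr2 by 4.78 (SE 0.33). Eomes (3.78), Tbx21 (2.81), Cd44 (2.60), Fasl (2.91) and Ifng (2.77) were higher. The size of the Ifng difference depended on 1 array, TMem 0 h replicate 1. It was 1.68 without that array, where Ifng was still called, and 4.49 with array weights. Il7r (-1.62), Klf2 (-1.37), Fas (-1.30), Prf1 (-0.75), Cd27 (-0.74), Lef1 (-0.64), Ccr7 (-0.58), Cd8a (-0.43) and Cd8b1 (-0.61) were lower. All 23 measured genes of S phase (adjusted p = 4.12e-30, adjusted p = 4.18e-05 with an estimated correlation) and all 23 of G2 and M phase (adjusted p = 2.55e-43, adjusted p = 1.88e-05 with an estimated correlation) were higher (23 and 23 adjusted over each list alone), among them Bub1 (5.48), Kif11 (5.31), Top2a (4.97), Ccna2 (4.93), Mki67 (4.79) and Rrm2 (4.32). Large falls were Kcnma1 (-6.29), Xist (-4.77), Trat1 (-3.86), Rgs2 (-2.73), Cpm (-2.62), Boll (-2.61), Slfn5 (-2.59) and Gria3 (-2.55). Ccr2, Fasl and Bub1 were near background in TN, and Xist, Trat1 and Boll in TMem.

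Of the effector transcription factors and receptors, 15 of 23 rose and 2 fell, 15 and 2 adjusted over the list alone in TMem at 0 h (adjusted p = 4.59e-10, adjusted p = 0.0894 with an estimated correlation), with Il12rb2 (3.85), Cxcr3 (3.76) and Bhlhe40 (3.53). IL-2 and STAT5 response (15 of 19 rose and 2 fell, 15 and 2 adjusted over the list alone, adjusted p = 1.30e-08, adjusted p = 0.00705 with an estimated correlation) and cholesterol synthesis (16 of 19 rose and 0 fell, 16 and 0 adjusted over the list alone, adjusted p = 7.89e-09, adjusted p = 0.0393 with an estimated correlation) were higher, with Socs2 (3.98), Il2rb (1.97), Sqle (1.56) and Cyp51 (1.52). With the preset correlation alone, granzymes (adjusted p = 4.74e-04, adjusted p = 0.172 with an estimated correlation), glycolysis (adjusted p = 8.95e-08, adjusted p = 0.0944 with an estimated correlation) and interferon gamma response (adjusted p = 3.64e-04, adjusted p = 0.226 with an estimated correlation) were higher. Higher too were ATF4 targets (adjusted p = 2.17e-04, adjusted p = 0.14 with an estimated correlation), hypoxia response (adjusted p = 0.0496, adjusted p = 0.439 with an estimated correlation), T cell activation (adjusted p = 0.00343, adjusted p = 0.235 with an estimated correlation) and cytokines (adjusted p = 0.0114, adjusted p = 0.249 with an estimated correlation). Naive and central memory genes (adjusted p = 1.05e-04, adjusted p = 0.203 with an estimated correlation), type I interferon response (adjusted p = 0.00364, adjusted p = 0.396 with an estimated correlation) and ribosomal proteins (adjusted p = 3.24e-09, adjusted p = 0.0944 with an estimated correlation) were lower. Lower too were fatty acid oxidation (adjusted p = 0.0316, adjusted p = 0.513 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.0316, adjusted p = 0.662 with an estimated correlation) and handling stress genes (adjusted p = 0.00759, adjusted p = 0.0944 with an estimated correlation). Asns rose 16-fold, Ifit3 fell by 2.19 and Fos by 1.76. The unfolded protein response was not called (adjusted p = 0.263), with Dnajb9 lower and Sdf2l1 (1.26) higher. The erythroid and platelet list was not called (adjusted p = 0.075), although Ppbp (2.00) and Pf4 (1.26) were higher. Of 2 mast cell and basophil genes chosen after their values were seen, Cpa3 had means of 9.42 in TMem and 6.17 in TN. Mcpt8 had means of 6.29 and 6.05.

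In total, 3659 genes were higher and 3492 lower in TMem than in TN at 0 h, with nonoverlapping groups for 35.8% of genes against 10% by chance. The count of 7151 was 4091 with only the 6 arrays compared and 12617 when every row of the table was tested. With only these arrays, Ccr7 (adjusted p 3.94e-10 to 0.0676), Prf1 (adjusted p 2.64e-06 to 0.0531) and Cd8a (adjusted p 2.00e-08 to 0.2) were not called. Cd8a was not called with quantile normalization or without TN 0 h replicate 2 or TMem 0 h replicates 1 or 2 either. Its log2 difference was -0.28 with quantile normalization, -0.70 with array weights and -0.66 without TMem 0 h replicate 3, and that of Prf1 was -0.44 without that array. Centring each array on its median moved every difference between TMem and TN at 0 h by -0.12. It gave 2660 genes higher and 5082 lower. The arrays of TN 0 h and TMem 0 h spread more than the others, with lowest correlations between arrays of a group of 0.978 and 0.984.

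A memory score was built from the 833 genes at least 1 higher and the 507 at least 1 lower in TMem than in TN at 0 h. Without mixing it moved from a mean of -0.42 in TN alone at 18 h to 0.98 in TN alone at 96 h. A rise of the score thus need not mark memory. In TN cells at 18 h the score was higher in mix than in alone by 0.09, which is 5.47% of the gap to TMem alone (exact permutation p = 0.1, n = 3). At 96 h it was higher by 0.34, or 40.9% of the gap (exact permutation p = 0.1). In TMem cells it was lower by 0.10 at 18 h, 5.74% of the gap to TN alone (exact permutation p = 0.2), and lower by 0.08 at 96 h, 10.2% of the gap (exact permutation p = 0.1). At 18 h it differed by 0.06 in TN without TN alone replicate 3 and by -0.05 in TMem without TMem alone replicate 1. A score of the stimulation response, taken from TMem cells, was higher in TN mix than in TN alone by 0.78 at 18 h, 53.8% of the gap to TMem alone, and by 0.55 at 96 h, 20.2% of the gap (exact permutation p = 0.1 each). In TMem cells the score taken from TN cells differed by 0.01 at 18 h (exact permutation p = 1) and was lower by 0.19 at 96 h (exact permutation p = 0.1). The latter is 85.8% of the gap to TN alone, a gap of 0.22, whereas at 18 h the difference pointed away from TN alone (-3.43% of the gap). The genes of the stimulation score were chosen on arrays that also set the far end of its gap. Its percentages of the gap thus depend on that choice. Differences depended on the genes used as well. With genes differing by at least 2 and with no minimum, the memory score differed by 0.27 and -0.05 in TN at 18 h, by 0.65 and 0.13 in TN at 96 h and by -0.04 each in TMem at 96 h. With no minimum it differed by -0.06 in TMem at 18 h. The stimulation score differed by 1.11 and 0.405 in TN at 18 h and by 0.971 and 0.187 in TN at 96 h. In TMem it differed by 0.134 at 18 h with genes of at least 2 and by -0.0977 at 96 h with no minimum.

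**Figure D3:**
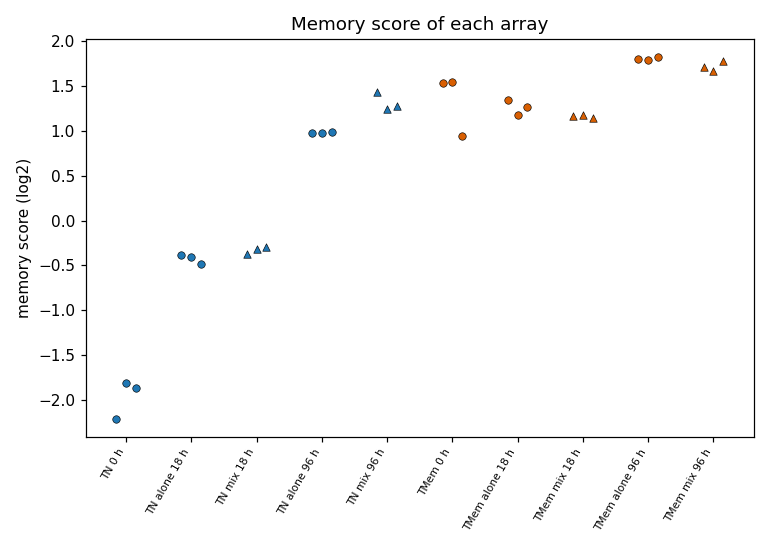
Memory score of each array, in log2 units: mean of the genes higher in TMem than in TN at 0 h minus mean of the genes lower. Blue, TN; orange, TMem; circles, 0 h and alone; triangles, mix; 3 arrays per group. The 0 h arrays were used to choose the genes; TN mix lay above TN alone by 0.34 at 96 h and by 0.09 at 18 h.

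TN cells stimulated alone differed widely from TN cells at 0 h. At 18 h against 0 h the chemokines Ccl3 (5.88) and Xcl1 (5.54), the transcription factor Irf4 (5.39), Gzmb (4.60), Rgs16 (4.52), Il2ra (4.49) and Ifng (4.14) rose. Large falls were Kcnma1 (-6.20), Slc16a5 (-3.23), H1f2 (-2.73), Clec12a (-2.60) and H2ac4 (-2.57). Eif2s3y, chosen after its values were seen, was higher by 3.95. A difference in donors thus cannot be separated from stimulation at 18 h against 0 h. Clec12a and H2ac4 were near background at 18 h and Eif2s3y at 0 h. T cell activation genes (18 of 19 rose and 1 fell, 18 and 1 adjusted over the list alone, adjusted p = 3.93e-20, adjusted p = 0.00235 with an estimated correlation) and ribosome assembly (22 of 24 rose and 0 fell, 22 and 0 adjusted over the list alone, adjusted p = 1.32e-18, adjusted p = 0.00534 with an estimated correlation) were higher, with Polr1b (2.21) and Mybbp1a (1.88). Fatty acid oxidation was lower (0 of 18 rose and 14 fell, 0 and 17 adjusted over the list alone, adjusted p = 4.28e-07, adjusted p = 0.158 with an estimated correlation). At 96 h Gzmb (6.02), Bub1 (5.32), Kif11 (5.02), Mki67 (4.84) and Top2a (4.82) rose and Trat1 (-2.83), Slfn5 (-2.81), Tcp11l2 (-2.70) and Chil5 (-2.68) fell, with Bub1 near background at 0 h and Chil5 at 96 h. All 23 genes of S phase (adjusted p = 6.90e-32, adjusted p = 2.78e-05 with an estimated correlation) and all 23 of G2 and M phase (adjusted p = 4.22e-41, adjusted p = 2.76e-05 with an estimated correlation) rose at 96 h, as did 17 of 19 of the IL-2 and STAT5 response (adjusted p = 1.14e-11, adjusted p = 0.00116 with an estimated correlation). Of the genes named above for other cell types, H2-Aa, Lyz2, Cpa3 and Foxp3 had higher means at 96 h than at 0 h. These were 9.46, 8.26, 8.58 and 8.79 against 6.52, 5.84, 6.17 and 6.81, and the genes were chosen after their values were seen. The counts of called genes were 3417 higher and 3328 lower at 18 h, and 3701 and 3561 at 96 h. When every row was tested they came to 13252 and 12785. Centring moved the differences by -0.14 at 18 h and by -0.11 at 96 h. It gave 2559 higher and 5973 lower at 18 h (2837 and 5566 with quantile normalization) and 2916 and 5333 at 96 h.

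In TMem cells stimulated alone, Il3 (6.43), Il2 (4.76), Idi2 (4.58), Plk2 (4.47) and Il1a (4.25) had large rises at 18 h and Cpa3 (-3.48), Ppbp (-3.12), Rasgrp2 (-3.09), Cd7 (-2.88) and Smpdl3a (-2.81) large falls. Il3, Il2, Idi2 and Il1a were near background at 0 h and Ppbp at 18 h. All 24 genes of ribosome assembly rose (adjusted p = 7.73e-25, adjusted p = 0.00145 with an estimated correlation), and 22 of 23 genes of G2 and M phase fell (adjusted p = 1.38e-14, adjusted p = 0.00447 with an estimated correlation), as did 21 of 25 of the type I interferon response (adjusted p = 7.44e-12, adjusted p = 0.0388 with an estimated correlation). The unfolded protein response was higher (15 of 18 rose and 1 fell, 15 and 1 adjusted over the list alone, adjusted p = 1.50e-10, adjusted p = 0.00506 with an estimated correlation). At 96 h the granzymes Gzmd (6.50), Gzme (5.62) and Gzmc (3.36) rose, with Havcr2 (3.68), Gpr141 (4.01) and Prf1 (3.04), while Cd7 (-3.08), Ppbp (-3.08), Itgae (-3.07), Slc28a2b (-2.95) and Slc6a19 (-2.74) fell. Gzmd and Gpr141 were near background at 0 h and Ppbp at 96 h. Naive and central memory genes were lower at 96 h (0 of 20 rose and 17 fell, 0 and 17 adjusted over the list alone, adjusted p = 3.05e-21, adjusted p = 0.00429 with an estimated correlation), and glycolysis (adjusted p = 1.40e-09, adjusted p = 0.0317 with an estimated correlation), hypoxia response (adjusted p = 1.46e-11, adjusted p = 0.00837 with an estimated correlation) and cholesterol synthesis (adjusted p = 3.60e-11, adjusted p = 0.00837 with an estimated correlation) were higher. The counts were 3588 higher and 3446 lower at 18 h and 3201 and 1683 at 96 h.

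After stimulation alone for 18 h, TMem exceeded TN cells widely in Il3 (6.19), H2ac4 (5.44), Mt2 (5.14), Havcr2 (4.89) and Scd1 (4.83) and lay far below in Xist (-5.90), Slc28a2b (-3.67), Slc6a19 (-3.36), Ifi209 (-3.12) and Tmem71 (-2.96). Here H2ac4, Havcr2 and Scd1 were near background in TN and Xist in TMem. At 96 h large differences were Gzmd (6.47), Scd1 (5.74), Gzme (5.38), Eif2s3y (5.10) and Ly6a2 (4.74) upward and Xist (-6.65), Kcnma1 (-5.44), Ifit3 (-4.33), Itgae (-4.08) and H2-Aa (-3.63) downward. Gzmd, Scd1 and Eif2s3y were near background in TN, and Xist in TMem, so that these 4 differences are lower bounds and have no order of size. Prf1 was higher in TMem at 18 h (1.43) and 96 h (4.09). At both times naive and central memory genes (adjusted p = 1.33e-15, adjusted p = 0.00853 with an estimated correlation at 18 h; adjusted p = 2.87e-19, adjusted p = 0.00452 with an estimated correlation at 96 h) and type I interferon response (adjusted p = 5.84e-19, adjusted p = 0.00853 with an estimated correlation; adjusted p = 4.02e-19, adjusted p = 0.00987 with an estimated correlation) were lower in TMem. Granzymes were higher (adjusted p = 2.49e-12, adjusted p = 0.00853 with an estimated correlation; adjusted p = 4.36e-18, adjusted p = 0.00141 with an estimated correlation). The counts were 3071 higher and 2688 lower at 18 h, and 2821 and 1599 at 96 h; the latter total of 4420 became 6699 with only the groups compared and 8205 with array weights.

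In mixed cultures, TMem still differed from TN cells. The cells of both types may come from the same cultures, and the fit took their arrays as independent. At 18 h H2ac4 (4.96), Rrm2 (4.49), Havcr2 (4.46), Csf2 (4.15) and Ccna2 (4.06) were higher in TMem than in TN and Xist (-5.11), Ifit3 (-2.36), Cxcl10 (-2.30), Ecm1 (-2.27) and Iigp1 (-2.22) lower, with H2ac4 and Havcr2 near background in TN. At 96 h Gzmd (5.36), Gzme (5.03), Havcr2 (4.77), Gpr141 (4.12) and Klrc1 (4.07) were higher and Xist (-6.27), Kcnma1 (-5.27), Trat1 (-2.45), Tlr7 (-2.20) and Iigp1 (-2.17) lower, with Gzmd, Havcr2 and Gpr141 near background in TN and Xist and Trat1 in TMem. Il7r was lower in TMem at 18 h (-0.96) and higher at 96 h (1.33). All 23 genes of G2 and M phase were higher in TMem at 18 h (adjusted p = 1.66e-57, adjusted p = 2.14e-06 with an estimated correlation), and granzymes were higher at 96 h (12 of 18 rose and 0 fell, 13 and 0 adjusted over the list alone, adjusted p = 6.44e-27, adjusted p = 2.76e-04 with an estimated correlation). The counts were 2348 higher and 1722 lower at 18 h and 1331 and 786 at 96 h, with totals of 6107 and 4909 with array weights.

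**Figure D4:**
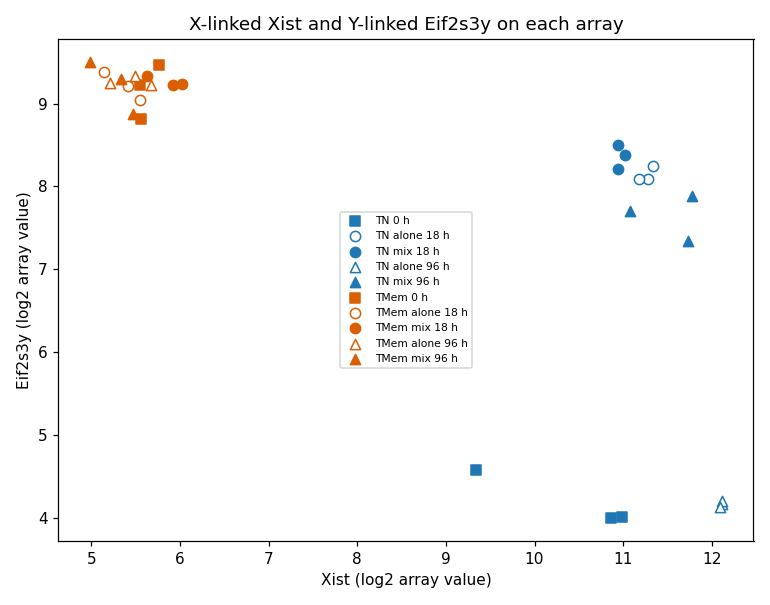
Log2 array values of X-linked Xist and Y-linked Eif2s3y on all 30 arrays. Blue, TN; orange, TMem; squares, 0 h; circles, 18 h; triangles, 96 h; filled, 0 h and mix; open, alone. TN alone and TN mix at 96 h had mean Eif2s3y values of 4.17 and 7.64.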

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

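The tests of other splits in this part were chosen only after the results were seen; the contrasts of effects were fixed in advance. All results here stand out because the difference between 2 effects of mixing was itself tested, by a contrast of the effects in the fit of all arrays.

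At 18 h the effect of mixing in TN differed from that in TMem for 1031 genes. The effects of TN exceeded those of TMem for Il3 (2.25), Tnfsf4 (1.85), Cd83 (1.83) and Gzmc (1.78), and lay below them for Slc28a2b (-1.66), Tmem71 (-1.72), Cd7 (-1.81) and Akr1c18 (-1.83). Splits of the arrays within each cell type gave as many genes in 7 of 100, the real one included, with up to 1615 in another split. All 6 others kept the real grouping of the TN arrays and so carry its effect along. These splits therefore cannot decide whether chance gives as many genes.

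At 96 h the effects differed for 705 genes. Those of TN exceeded those of TMem for Scd1 (4.44), Eif2s3y (3.52), Mt2 (3.50) and Ak4 (3.31), and lay below them for Lyz2 (-2.58), Ifng (-2.61), Ifit3 (-2.62) and H2-Aa (-2.91). Scd1 and Eif2s3y were near background in TN alone, and Lyz2 in TN mix and both TMem groups. For Ifit3 the effects were opposite, -1.47 in TN and 1.14 in TMem. Since Eif2s3y is Y-linked, a difference in donors cannot be separated from the effect of mixing in TN at 96 h. Again 7 of 100 splits gave as many, the real one included, with 1534 as the highest of the others. Here too all 6 others kept the real grouping of the TN arrays and so carry its effect along, so these splits cannot decide on chance either. The highest kept both real groupings with the sign of 1 effect turned, and so counts genes by the sum of the effects, as did the highest in the contrast of times below.

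In TN the effect at 96 h differed from that at 18 h for 2475 genes. It was higher at 96 h for Scd1 (4.13), Eif2s3y (3.26), Aldoc (3.01) and Bnip3 (2.98), and lower for Cd74 (-2.56), H2-Aa (-2.62), Il3 (-2.64) and Ifng (-3.45). Il3 was near background in both TN groups at 96 h and Scd1 in TN mix and TN alone at 18 h. A difference in donors at 96 h cannot be separated here either, since Eif2s3y is Y-linked. Here 2 of 100 splits gave as many, the real one included, a share under 0.05, with 2878 as the highest other. The splits exchange mix and alone within each time, so they stand for no effect of mixing at either time. They therefore cannot decide whether the effects at the 2 times differ.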

How the results depend on the processing

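The 3 settings that leave out the 0 h arrays, leave out genes of X and Y, or take pairs of TN arrays at 96 h as a block were chosen after seeing the data; the others were fixed in advance. Arrays measure signal over a background that is not known here, so small differences of dim genes can be compressed to an unknown degree, and genes near background can be missed. Of 302 alternatives for 16 counts of genes, 250 lay within 1.5 times the count reported; so did 53 of 60 for counts of lists. Of 888 for 74 called lists, 735 kept the call and 153 lost it. Of 88 for scores, 76 moved by less than 1 SD, and of 56 for agreement, 39. Of 5192 for 357 values of named genes, 5070 kept their side of the threshold, 98 lost the call and 24 gained it. No called gene or list turned direction. Unless the construction of an alternative shows the cause, the cause was not tested.

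With array weights the counts were 4853 and 6343 (TN mix against alone, 18 h and 96 h), 100 and 906 (TMem), 8205 (TMem against TN alone, 96 h), 6107 and 4909 (in mix, 18 h and 96 h), and 2941, 3202 and 5147 (differences between effects). Requiring a difference of at least 1 left fewer genes by construction: 116 and 189 (TN), 1 and 7 (TMem), 1340 (TMem against TN, 0 h), 1142 and 1482 (TN against 0 h), 1352 and 495 (TMem against 0 h), 1125 and 634 (TMem against TN alone), 677 and 297 (in mix), and 149, 170 and 347 (differences between effects). With the 0 h arrays left out, counts were 3208 (TN, 96 h), 41 and 507 (TMem), and 2089, 1422 and 3872 (differences between effects). With every row tested they were 3 (TMem, 18 h), 12617 (TMem against TN, 0 h), and 13252 and 12785 (TN against 0 h), with more rows tested by construction. With only the groups compared they were 36 and 435 (TMem), 4091 (TMem against TN, 0 h), 6699 (TMem against TN alone, 96 h), and 1961 and 1185 (differences between effects at 18 h and 96 h). The replicate block gave 2769, 2014, 6 and 213 in the comparisons of mix with alone and ended 2 calls of named genes, Pdcd1 in TMem and Il17rb in TN at 96 h, and no other.

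Leaving out single arrays, which leaves fewer arrays by construction, gave 1897 to 2496 genes (TN, 18 h), 1 to 6 (TMem, 18 h) and 105 to 170 (TMem, 96 h). The correlation of effects ran from -0.0464 to 0.058 between TN and TMem at 18 h and from 0.0972 to 0.212 at 96 h, from 0.00457 to 0.134 between times in TN and from -0.0413 to 0.0941 in TMem. Lists called with an estimated correlation were 0 and 9 (TN), 6 and 5 (TMem) and 4 (TMem against TN, 0 h), and with fry 0 and 6 (TMem, 18 h and 96 h). The memory score with genes of at least 2 and with no minimum was 0.273 and -0.0486 (TN, 18 h), 0.651 and 0.128 (TN, 96 h), and -0.0436 and -0.0422 (TMem, 96 h). The stimulation score was 1.11 and 0.405 (TN, 18 h) and 0.971 and 0.187 (TN, 96 h), 0.134 (TMem, 18 h, at least 2) and -0.0977 (TMem, 96 h, no minimum). With the dim filter, agreement was 0.225 between TN and TMem at 96 h, 0.0972 between times in TN and 0.0807 between times in TMem.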

Other observations

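The tests of the 3 patterns below, and the tests of other splits, were chosen only after the results were seen.

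In TN mix at 96 h, Y-linked transcripts were present that lay near background in TN alone at 96 h. Their levels would correspond to shares of TMem RNA of 0.313 (Eif2s3y), 0.347 (Kdm5d) and 0.319 (Uty). The shares given by 28 genes at least 8-fold higher in TMem mix than in TN alone had a lower quartile of 0.00908, a median of 0.134 and an upper quartile of 0.310, and 15 of the 28, Gzmd (0.0114) and Gzme (0.00347) among them, lay below 50% of the lowest Y-linked share, which argues against TMem cells or their RNA as the source of the Y-linked transcripts. On the other side 7 of the 28 lay above the highest Y-linked share, with Scd1 at 0.398, Mt2 at 0.421 and Bnip3 at 0.607. Naive donors of both sexes in the mixed cultures may explain the pattern, which stays open: Xist lost a share of 0.332, but of 0.216 without TN mix 96 h replicate 2 (Y-linked shares of 0.306 to 0.336), and it differed by 1.71 on the log2 scale between TN 0 h and TN alone at 96 h, which both had Y-linked transcripts near background, against its fall of 0.58. A difference in donors cannot be separated from that of culture in this comparison, and with genes of X and Y left out 2055 genes were called at 96 h against 2117. TN at 18 h carried these transcripts and TN at 0 h did not, so comparisons of these groups are touched as well. In TN alone at 18 h, cultured without TMem cells, a mean Eif2s3y of 8.14 stood beside a mean Xist of 11.27. Y-linked transcripts thus occurred there without TMem cells in the culture, which leaves donors of both sexes open for 96 h too.

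At 96 h TN alone held more MHC class II transcripts than TN mix, with log2 differences from -2.83 to -1.09 for 4 genes. The 11 other B cell genes had a median difference of 0.112 and a lower quartile of 0.0552, so most of them did not fall. However, 1 of them, Cd79b, fell by 0.70, and the whole list was lower (camera, adjusted p = 0.0475 with an estimated correlation). The 8 CD4 T cell genes other than Foxp3 and Izumo1r had a median of 0.0677, with Cd4 at 0.12. Of these, 2, Tnfsf8 (-0.72) and Il17rb (-0.30), were called lower, and the whole list was lower (camera, adjusted p = 0.0367 with an estimated correlation). These medians show no common fall of the markers of either cell type. A median does not exclude a small number of such cells, so B cells and CD4 T cells stay open. For the cells below, calls and camera were used instead of a median. Macrophages, monocytes, dendritic cells or neutrophils, of whose list 3 of 22 members were called lower, could contribute and cannot be told apart from a change in the T cells. The same holds for mast cells or basophils, since Cpa3 (8.58 in TN alone, 6.85 in TN mix) and Mcpt8 (7.54 and 6.23) fell and, of 17 other markers written down after these values were seen, 3 were called lower and 0 higher (Kit, Ms4a2, which was near background in both groups and not called without TN alone 96 h replicate 3, and Prss34, not called without TN alone 96 h replicate 2 or TN mix 96 h replicate 2), with p = 0.15 as a set by camera with an estimated correlation. In TMem at 0 h the mean of Cpa3 was 9.42 and that of Mcpt8 6.29, so these 2 genes did not go together there. Per the labels every group was sorted, which would remove other cells, and the gates are not given in the sources used here.

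TN mix had a larger stimulation response than TN alone at 18 h. Carry-over of TMem RNA as the source is argued against. The median share of TMem RNA from 47 genes at least 8-fold higher in TMem mix was 0.0121 with an upper quartile of 0.0248, whereas the 31 called genes 2-fold higher in TN mix would need a median share of 0.871. Of these, 14 were no higher in TMem mix than in TN mix. Without the outlying replicate 2 of TN mix 18 h, 2325 genes were called against 2881 with it, so that array was not the whole cause. What remains is a biological difference by culture, which may be the cause, as a hypothesis found and tested on the same data, with any difference between cultures that was not recorded still open.

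For comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. In each of the 13 comparisons 1 split, the real one, gave as many genes. Given here as the real count and the highest other, they were 2881 and 0 (TN mix against alone, 18 h) and 2117 and 1 (96 h). In the latter, arrays with the same number had correlated deviations, and splits that part as many of these pairs gave at most 1. For TMem mix against alone they were 6 and 1 (18 h) and 223 and 0 (96 h). Against 0 h they were 6745 and 1 (TN, 18 h), 7262 and 1 (TN, 96 h), 7034 and 3 (TMem, 18 h) and 4884 and 0 (TMem, 96 h). For TMem alone against TN alone they were 5759 and 0 (18 h) and 4420 and 0 (96 h). For TMem mix against TN mix they were 4070 and 0 (18 h) and 2117 and 70 (96 h). For TMem against TN at 0 h they were 7151 and 1208. That other split set TMem replicates 1 and 2 and TN replicate 1 against the rest, and it points to a structure of the 0 h arrays.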
